A study of Schmidtea mediterranea with 144 samples.

How the data were processed

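RNA sequencing was done on whole planarians (Schmidtea mediterranea, asexual strain CIW4) and on X1 cells, the cycling stem cell fraction that Hoechst staining and flow cytometry isolate. Per the labels' protocols, worms were fed bacteria carrying double-stranded RNA against Egfr3, nrg6, nrg7 or the control Unc22, and polyA-selected libraries were made from 500 ng of total RNA with 4 biological replicates per stage. The sample labels give 3 feedings for NT day 9, 6 for SR worms and 8 for NT day 30 and X1 cells, while the treatment protocol states 6 for all RNAi experiments; which holds was not settled here. The submitters' processing notes name CASAVA 1.8.2, Bowtie and edgeR, with no role or order; the transcript models and their build are not given in the sources used here. The values are RPKM, deposited by the authors as a single table of 35195 transcripts in 144 libraries, and every column name equals the title of 1 sample. No column of per-sample values was left unused (0 columns).

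The RPKM values were whole multiples of what 1 read is worth, so transcript lengths, reads and the library sizes behind the deposited RPKM were recovered from them. All values (100%) came out whole within 1e-06 reads. Lengths ran from 58 to 23779 bases with a median of 858. The recovered libraries held 14.54 to 22.9 M reads (median 18.44 M, 2662 M in all). The ratio of each library size used by the authors to the recovered reads, a normalization factor, had a geometric mean of 1.0 and ran from 0.75 to 1.158 in whole worms and from 0.766 to 0.895 in X1 cells. No replicate pair agreed within sampling noise, so each library counted once.

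Transcripts with an RPKM of at least 1 in at least 4 libraries of a fit were tested on log2(RPKM + 1) with limma 3.58.1 in R 4.3.3, using a group-mean design and a variance trend with level; p-values were adjusted by Benjamini and Hochberg, and an adjusted p under 0.05 counted as a difference. A fold change is on the log2(RPKM + 1) scale, which understates the change of low transcripts. All whole-worm libraries shared 1 fit (24861 transcripts), the 16 X1 libraries another (19433 transcripts), and X1 against whole worms was fitted on its 8 libraries (21958 transcripts). The whole worms of SR days 6, 8 and 10 were averaged with equal weight. The same steps were tested on simulated reads with 200 changed transcripts. Apart from those changes, all libraries were drawn around 1 mean per transcript, with a single dispersion for all transcripts. The simulated reads hold no library that stands apart from its group, so the shares recovered may be higher than in the real data. For Egfr3 on SR days 6 to 10 (24325 transcripts), 97% of 2-fold and 88% of 1.5-fold changes were recovered. For Egfr3 in X1 cells (19275 transcripts) the shares were 80% and 26%, and for Egfr3 in NT worms on day 30 (24331 transcripts) they were 80% and 28%.

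The files do not pair transcript IDs with gene names. The targeted transcripts could therefore not be looked up, and the gene lists of cell type markers that had been fixed in advance were not used. Lists were defined from the libraries instead. The X1-high list holds the 200 transcripts most enriched in Unc22 X1 cells over Unc22 NT worms of day 30. The radiosensitive list holds the 200 that fell most in Unc22 worms from SR day 0 to day 4. The X1-low list and the radiation-raised list, their opposites, and the early-lost and later-lost lists were added after the data were seen. A list score is the mean of log2(RPKM + 1) over the list in a library. Scores were compared with 2-sided exact permutation tests that relabelled libraries within a day. The planned family held 35 tests and the added family 33. For 4 libraries against 4, the smallest p possible is 0.0286. With the p-values found in the planned family it adjusted to 0.0667, so no such test passed after adjustment. Lists were also tested with limma's camera, with a preset correlation between transcripts and with an estimated one, and with its rotation test fry, which asks whether a list moves 1 way on balance and does not compare it with other transcripts. The family held 46 list tests. Named transcripts are the 2 with the largest rise and the 2 with the largest fall among those that pass these filters. They have an adjusted p under 0.05, at least a 2-fold change and a mean RPKM of at least 1 in the higher group. Where 4 libraries were compared with 4, the groups also do not overlap, which happens in 2 of 70 relabellings by chance. Where several days were averaged, only the day means were compared, so single libraries may overlap. For an effect minus that on day 0, overlap was not checked.

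The labels give replicate numbers 1 to 4 in each group. Correlations of deviations from the group means exceeded 0.1 in all 4 pairs for Egfr3 and Unc22 at SR day 0 (0.292 to 0.407), day 4 (0.277 to 0.373) and day 8 (0.323 to 0.385), for nrg6 and Unc22 in X1 cells (0.166 to 0.232), and for Unc22 at day 0 with day 4 (0.302 to 0.392) and day 8 (0.298 to 0.391). In these comparisons the numbers were taken to pair the libraries, from the data and not from the labels. The groups concerned are those that part 2 and 2 on a shared profile given below, which alone can give such correlations. On each of these days 3 of 4 Unc22 libraries correlated best with the Egfr3 library of their own number. For nrg6 in X1 cells 2 of 4 did, and for Unc22 at day 0, 2 of 4 with day 4 and 1 of 4 with day 8. Pairs of single libraries are therefore not settled. The counts and scores reported still come from fits and relabellings without pairs, and paired values are given beside them where they change a call. Simulated values for shared controls used the spread without replicate 4 of nrg6 SR day 1. In the other comparisons the libraries share only a number.

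Alternatives chosen before the data were examined were a pseudocount of 0.1, no filter, quantile normalization, rescaling by the median ratio, a replicate block, a fit of only the groups compared, lists of 100 and 500, the median over a list, and leaving out each library. Chosen after the data were seen were limma-voom on the recovered reads, removal of the trend with transcript length, a replicate block in a fit of only the groups compared, leaving out replicate 4 of nrg6 SR day 1, a batch term for 16 libraries that share a profile (replicates 3 and 4 of Egfr3 and Unc22 at SR days 0, 4 and 8, and replicates 1 and 2 of nrg6 and Unc22 in X1 cells), leaving those 16 out, X1 enrichment from the other knockdowns and an X1-low list over all RNAi groups where a comparison shares the Unc22 libraries that defined them, and the batch term together with leaving out that library. Figures were drawn with matplotlib 3.10.9.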

Results

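Transcripts were measured by RNA sequencing in 36 groups of 4 replicate libraries, 144 in all, from planarians fed RNAi food against Egfr3, nrg6, nrg7 or the control Unc22. NT worms were not irradiated and were collected on day 9, after 3 RNAi feedings per the sample labels, and on day 30, after 8. SR worms had 6 feedings, received a sublethal dose of 1250 rads, and were collected 0, 1, 4, 6, 8 and 10 days later. X1 cells, the cycling stem cells (neoblasts), were sorted on day 30, after 8 feedings. Libraries held 14.54 to 22.9 M reads. In 8 of the groups, 2 of the 4 libraries shared a profile that set them apart from the other 2: replicates 3 and 4 of Egfr3 and Unc22 at SR days 0, 4 and 8, and replicates 1 and 2 of nrg6 and Unc22 in X1 cells. These 16 libraries lay between -0.96 and -0.52 on that profile, and their 16 partners between 0.010 and 0.178. The groups and the 16 libraries were picked by this profile, which Egfr3 and Unc22 at SR day 0 defined, so the gap follows in part from the choice. Counts that these libraries moved are given also with a batch term for them.

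**Figure D1:**
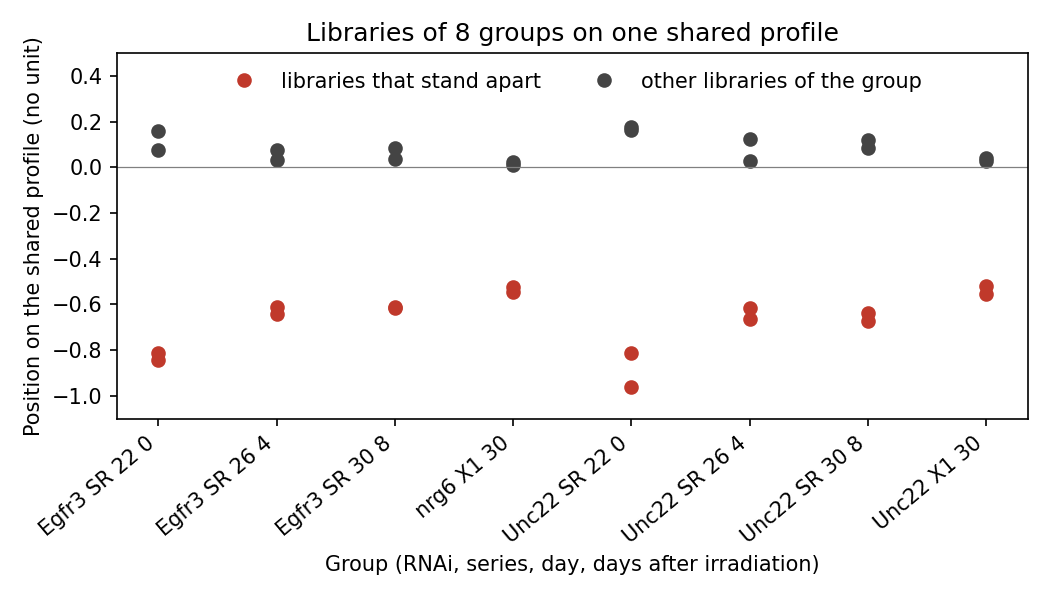
Each point is 1 library of the 8 groups, and the vertical axis is its position (no unit) along the profile found at SR day 0, relative to the other RNAi groups of its stage. The 16 libraries in red lie between -0.96 and -0.52 and the other 16 between 0.010 and 0.178. The red libraries were picked by this position.

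The first comparison asked which transcripts mark the stem cell fraction in control animals. In Unc22 X1 cells 8477 of 21958 transcripts were higher and 10140 lower than in Unc22 NT worms of day 30, of which 5177 and 7063 changed at least 2-fold. SMED30029780 rose most among the X1-high list, from 2.88 ± 0.28 RPKM in whole worms to 280.2 ± 13.4 in X1 cells (SD, n = 4 each; log2 fold change 6.18, limma adjusted p = 2.18e-11). SMED30010350 fell from 3219 ± 282 RPKM to 2.51 ± 2.11 (SD, n = 4 each; log2 fold change -10.02, limma adjusted p = 1.59e-09). The split of higher and lower calls depended on the scaling: quantile normalization gave 10581 higher and 8246 lower.

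After irradiation of control worms most X1-high transcripts were lower within a day, and their level was lowest on day 4 and higher again by day 10. The X1-high score of Unc22 worms was 2.84 ± 0.08 on day 0, 1.54 ± 0.04 on day 1, 1.21 ± 0.04 on day 4, 1.31 ± 0.02 on day 6, 1.55 ± 0.08 on day 8 and 1.802 ± 0.06 on day 10 (SD, n = 4 each). Of the 197 members tested, 187 had fallen on day 1 (2 rose), 189 on day 4 (0 rose) and 186 on day 10 (2 rose), with medians of -1.22, -1.50 and -1.01 on the log2 scale. Members of the X1-low list moved the other way, with 150 of 200 higher and 0 lower on day 4 (camera adjusted p = 0.00854 with an estimated correlation); on day 8, when 116 were higher and 10 lower, that adjusted p was 0.0519 and the call was lost. Of all transcripts, 2500 were higher and 2389 lower on day 1, 3499 and 2843 on day 4, 3623 and 3295 on day 6, 2307 and 2524 on day 8, and 2702 and 2910 on day 10. Without the 16 libraries of the shared profile, which leaves fewer libraries, 3215 differed on day 1, 3914 on day 4 and 2903 on day 8. Among those that were lower on day 4 and had a value for X1 enrichment, 84.9% were enriched in X1 cells, against 37% of the transcripts tested. SMED30007406 fell from 132.1 ± 5.7 RPKM on day 0 to 5.21 ± 0.83 on day 4 and SMED30011307 rose from 11.5 ± 6.4 to 248 ± 102 (SD, n = 4 each). The fall of the X1-high list held in limma's camera test on every day, also with an estimated correlation (adjusted p = 3.63e-16 on day 10, the weakest). Each day's score differed from day 0 in all 4 libraries (exact permutation p = 0.0286, the smallest possible; adjusted p = 0.0667, which misses the threshold). On days 4 and 8, where replicate numbers were taken to pair with those of day 0, the paired exact p was 0.125, the smallest that 4 pairs allow.

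After irradiation, the X1-high transcripts of Egfr3 RNAi worms were at a lower level than in control worms on days 6 to 10, with no difference detected on day 0. Their score was 2.81 ± 0.07 on day 0, 1.47 ± 0.05 on day 1, 1.10 ± 0.03 on day 4, 1.07 ± 0.01 on day 6, 1.16 ± 0.02 on day 8 and 1.20 ± 0.06 on day 10 (SD, n = 4 each). Over days 6 to 10 it was lower than in Unc22 by 0.41 (1.14 against 1.55, n = 12 each; exact permutation p = 5.83e-06, the smallest possible; adjusted p = 0.000204), and on each of these days all 4 Egfr3 libraries lay below all 4 Unc22 libraries. So they did on day 4, when the difference was -0.113 (exact permutation p = 0.0286, adjusted p = 0.0667, n = 4 each; paired exact p = 0.125, the smallest 4 pairs allow; -0.092 with quantile normalization, exact permutation p = 0.0857). On day 0 the difference was -0.03 (exact permutation p = 0.657, n = 4 each). Of the 197 X1-high members, 140 were lower and 3 higher over days 6 to 10 (168 lower and 3 higher when adjusted over the list alone), and camera gave an adjusted p of 2.09e-21 with an estimated correlation. Of all transcripts, 372 were lower and 103 higher, and 30 of the lower ones changed at least 2-fold. Among the lower ones, 68.3% were enriched in X1 cells against 37% of those tested (Fisher's exact test over transcripts, which are not independent, adjusted p = 2.39e-34). Of the 372, 259 had also fallen by day 4 in control worms, against 2843 of all 24861 transcripts tested. SMED30035904 had 7.35 ± 2.72 RPKM against 63.2 ± 30.7 in Unc22 and SMED30007406 had 2.77 ± 1.41 against 21.5 ± 11.8 (SD over 3 days, n = 12 each; log2 fold changes -2.84 and -2.46). With the batch term the count was 570, and without replicate 4 of nrg6 SR day 1, a library outside this comparison that widened the shared spread, it was 797. The effect on days 6 to 10 minus that on day 0 was itself tested and called 71 transcripts, 65 of them lower, and 42 of the 65 lower and 3 of the 6 higher ones belonged to the X1-high list. Adjusted over the list alone, 99 of its 197 members were lower and 3 higher. Camera gave this difference an adjusted p of 1.7e-13 with an estimated correlation. Without the 16 libraries the count was 45.

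**Figure D2:**
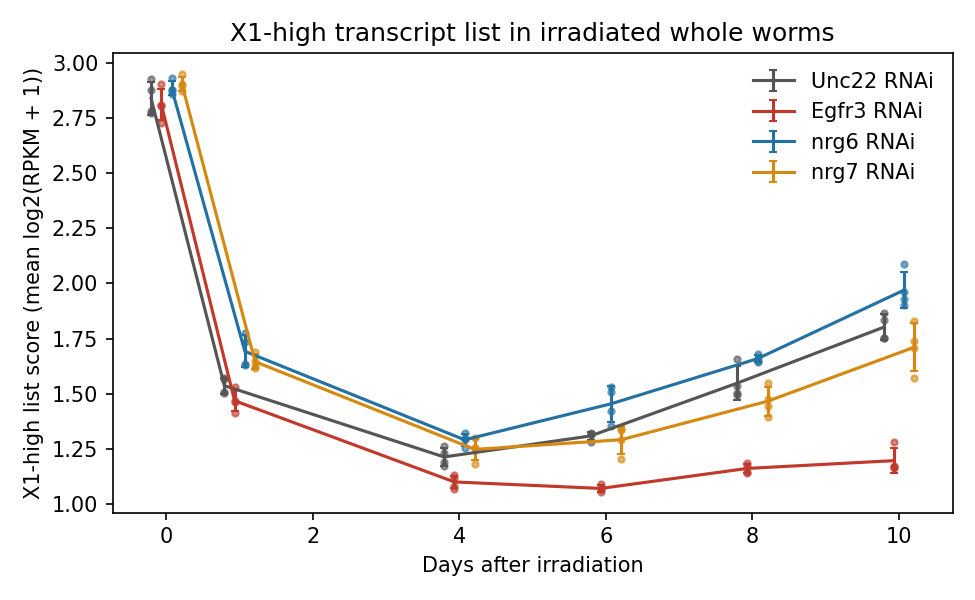
The horizontal axis is days after irradiation and the vertical axis is the X1-high score, the mean log2(RPKM + 1) over the 200 transcripts of the list. Points are libraries, and lines join the means with SD (n = 4). Egfr3 RNAi worms stayed at 1.20 on day 10 while Unc22 worms had reached 1.802.

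Worms given nrg6 RNAi had more of the X1-high transcripts than control worms on SR days 6 to 10, and the scores of earlier days lay above control too. The difference was 0.046 on day 0 (exact permutation p = 0.257), 0.156 on day 1 (exact permutation p = 0.0286, adjusted p = 0.0667) and 0.077 on day 4 (exact permutation p = 0.0571, n = 4 each). The day 0 value depends on the shared profile. Unc22 replicates 1 and 2 scored 2.774 and 2.78, and replicates 3 and 4, of the 16 libraries, 2.875 and 2.927. The nrg6 libraries scored 2.858 to 2.932, all above replicates 1 and 2 but not all above 3 and 4. On day 1 all 4 nrg6 libraries lay above all 4 Unc22 libraries, and without replicate 4 of nrg6 SR day 1 the difference was 0.128 (exact permutation p = 0.0286). Without Unc22 replicate 1 or 2, with 3 libraries left in that group, it was 0.147 or 0.144 (exact permutation p = 0.0571 each). Over days 6 to 10 the score averaged 1.69 against 1.55, higher by 0.142 (n = 12 each; exact permutation p = 1.75e-05, adjusted p = 0.000306). Of the 197 members 33 were higher and 0 lower (79 higher and 1 lower when adjusted over the list alone), and camera gave an adjusted p of 6.84e-06 with an estimated correlation. Of all transcripts, 151 were higher and 70 lower. The named fall was SMED30017199, at 2.10 ± 0.32 RPKM against 6.77 ± 0.97 (SD, n = 12 each; log2 fold change -1.32). The count was 229 with the batch term and 660 without replicate 4 of nrg6 SR day 1. The effect minus that on day 0 called 6 transcripts, 3 higher and 3 lower (9 and 4 with quantile normalization, 2 and 0 with the median ratio); camera's adjusted p for the X1-high list in it was 0.0811 with an estimated correlation. Single libraries moved this count: it was 14, 0, 2 and 1 without nrg6 SR day 0 replicates 1, 2, 3 and 4, 19, 2 and 1 without Unc22 SR day 0 replicates 2, 3 and 4, and 74 without replicate 4 of nrg6 SR day 1. It was 3 without replicate 2 or 4 of nrg6 SR day 6 or day 8, replicate 1 or 2 of nrg6 SR day 10, replicate 2 of Unc22 SR day 6 or day 8, or replicate 3 of Unc22 SR day 10.

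Worms given nrg7 RNAi differed from control worms on SR days 6 to 10 in many transcripts, most by small amounts. Here 891 transcripts were higher and 452 lower, with a median size of 0.20 on the log2 scale, and 24 of the higher ones changed at least 2-fold. Quantile normalization gave 895 higher and 795 lower. Of the higher ones 82.8% were depleted in X1 cells, against 47.4% of those tested, and of the 200 radiation-raised transcripts 109 were higher and 0 lower. Of these 200, 17 were also higher on day 0 and 0 lower (n = 4 each). The list was chosen for low values in these Unc22 libraries of day 0, which in part raises that count. SMED30029247 had 22.7 ± 14.4 RPKM against 2.90 ± 2.62 and SMED30007501 had 50.7 ± 26.0 against 9.24 ± 8.97 (SD, n = 12 each). The X1-high score was lower by 0.063 (1.49 against 1.55, n = 12 each; exact permutation p = 0.0336), which did not pass after adjustment (adjusted p = 0.0735; camera adjusted p = 0.0811 with an estimated correlation), and without the 16 libraries the difference was -0.05 (exact permutation p = 0.109). The rotation test fry, which asks only whether the members moved 1 way on balance, gave an adjusted p of 0.00521. On day 1 the score was higher than in Unc22, by 0.108 (exact permutation p = 0.0286, adjusted p = 0.0667, n = 4 each). The count was 1392 with the batch term and 3008 without replicate 4 of nrg6 SR day 1. The effect minus that on day 0 called 9 transcripts, and 0 without the 16 libraries; camera gave the X1-high list in it, lower, an adjusted p of 0.0298 with an estimated correlation. It called 5, 5 and 3 without nrg7 SR day 0 replicates 1, 2 and 3, 5 without nrg7 SR day 8 replicate 4, 15, 15 and 2 without Unc22 SR day 0 replicates 1, 2 and 3, and 28 without replicate 4 of nrg6 SR day 1.

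In worms at SR day 0, before the loss of stem cell transcripts, few transcripts separated Egfr3 RNAi from control (9 higher and 21 lower), while 629 were higher and 136 lower for nrg6 and 182 and 55 for nrg7. SMED30009725 had 1.94 ± 2.57 RPKM under nrg6 RNAi against 10.4 ± 3.2 in Unc22, and SMED30020792 had 0.62 ± 0.12 under nrg7 RNAi against 3.10 ± 0.86 (SD, n = 4 each). SMED30020792 went the other way under nrg7 RNAi on NT day 9, with 8.53 ± 8.47 RPKM against 1.605 ± 0.448 in Unc22 (SD, n = 4 each). Quantile normalization gave 25 higher and 29 lower for Egfr3, 685 and 347 for nrg6, and 402 and 324 for nrg7. The counts for nrg6 and nrg7 depended on the 16 libraries of 1 profile, which hold replicates 3 and 4 of the Unc22 group and no nrg6 or nrg7 library of that day. With the batch term they were 134 and 102, without the 16 libraries 51 and 78 (17 for Egfr3), and in a fit of only the groups compared 15 and 7 (4 for Egfr3). Without Unc22 replicates 1, 2, 3 and 4 in turn the nrg6 count was 1197, 1679, 39 and 189 and the nrg7 count 472, 808, 34 and 120. Without nrg6 replicates 2, 3 and 4 it was 243, 340 and 197, and without nrg7 replicates 1, 2, 3 and 4 it was 580, 112, 36 and 46. Without replicate 4 of nrg6 SR day 1 the counts were 68 for Egfr3, 3222 for nrg6 and 1884 for nrg7.

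In NT worms the radiosensitive scores were compared with those of control worms in exact tests with 4 libraries a side, and none passed the threshold. In the planned family even the smallest p that so few libraries allow did not pass after adjustment. On day 30 the radiosensitive score was 3.42 ± 0.03 in Egfr3, 3.42 ± 0.05 in nrg6 and 3.41 ± 0.05 in nrg7, against 3.38 ± 0.07 in Unc22 (SD, n = 4 each), and the exact permutation p-values were 0.314, 0.4 and 0.514. On day 9 the differences from Unc22 were -0.07, -0.08 and 0.06 (exact permutation p = 0.114, 0.143 and 0.257, n = 4 each). Camera called the list in all 6 comparisons with the preset correlation, lower for Egfr3 and nrg6 on day 9 and higher otherwise, and in 0 with an estimated one (adjusted p = 0.131 for nrg7 on day 9 and 0.395 to 0.452 in the others). Fry called it higher for nrg7 on day 9 (adjusted p = 0.0322) and gave adjusted p of 0.367 to 0.422 in the others. The radiation-raised list, the opposite one, was also higher for nrg7 on day 9 by fry (adjusted p = 0.0266), with 8 of 200 members higher and 0 lower (42 and 1 when adjusted over the list alone), while camera gave an adjusted p of 0.0811 with an estimated correlation. In the other 5 NT comparisons fry gave that list adjusted p of 0.0836 to 0.827. On day 9, 9 transcripts differed for Egfr3, 22 for nrg6 and 55 for nrg7, and on day 30, 37, 25 and 350; these days differ in the number of feedings as well as in time, and the difference between them was not tested. Quantile normalization gave 6 higher and 5 lower for Egfr3 on day 9 (6 and 3 otherwise) and 26 and 17 for nrg7 (43 and 12 otherwise). On day 30, 156 transcripts were higher and 194 lower in nrg7. Quantile normalization raised this count by over 1.5 times, and a replicate block in a fit of only the groups compared lowered it by over 1.5 times. With X1 enrichment taken from the Egfr3 and nrg6 libraries, which share none with this comparison, 58.2% of the higher and 11.9% of the lower ones were enriched in X1 cells, against 38.8% of those tested (Fisher's exact test over transcripts, adjusted p = 1.57e-06 and 1.12e-16), and 84.5% of the lower ones were depleted, against 50.9% (adjusted p = 2.14e-22). SMED30013692 stood at 1299 ± 116 RPKM in nrg7 worms of day 30 against 68.7 ± 6.5 in Unc22 (SD, n = 4 each; log2 fold change 4.22, limma adjusted p = 1.66e-72). SMED30017456 was lower under Egfr3 RNAi at all 8 whole-worm stages, at 1.501 against 8.85 RPKM on average. Without replicate 4 of nrg6 SR day 1 the day 9 counts were 67, 48 and 342 and the day 30 counts 104, 57 and 1064. With the batch term nrg7 had 99 on day 9 and nrg6 had 44 on day 30. Single libraries of the compared groups moved these counts too: the nrg7 day 9 count was 13 without nrg7 replicate 1, 100 without replicate 2, 29 without Unc22 replicate 1 and 21 without Unc22 replicate 4. The nrg7 day 30 count was 228 and 205 without nrg7 replicates 2 and 3, and 231 and 220 without Unc22 replicates 2 and 3. The nrg6 day 9 count was 41 without nrg6 replicate 1 and 13, 13 and 12 without Unc22 replicates 1, 3 and 4, its day 30 count was 16 without nrg6 replicate 4, and the Egfr3 day 30 count was 23 without Egfr3 replicate 4 and 22 without Unc22 replicate 2.

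**Figure D3:**
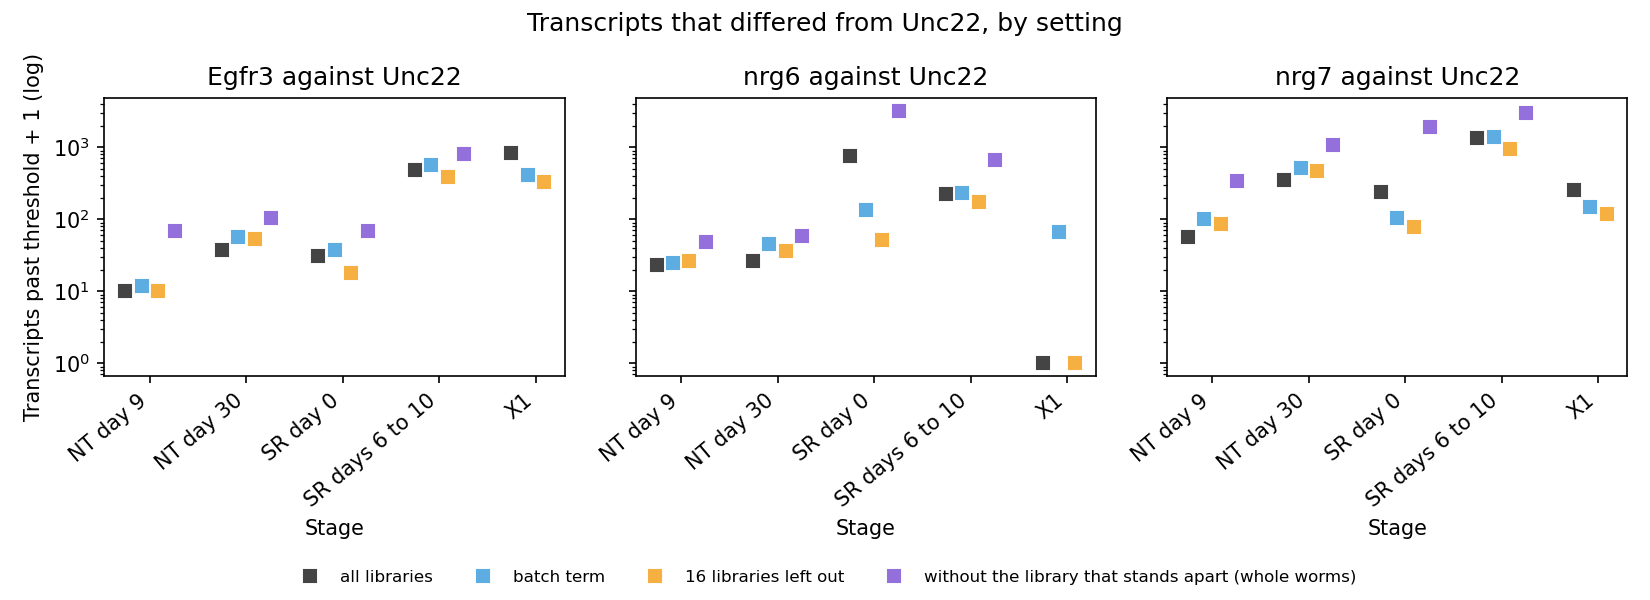
Each square is a count of transcripts that differed from Unc22, plus 1, on a log axis, by stage and RNAi; colours give the setting. Counts at SR days 6 to 10 stayed within 1.5 times under the batch term, while those of nrg6 and nrg7 at SR day 0 fell from 765 and 237 to 134 and 102.

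In X1 cells single transcripts differed from control for Egfr3 and nrg7, while none of the exact tests of the radiosensitive scores passed the threshold. In the planned family even the smallest p that so few libraries allow did not pass after adjustment. The radiosensitive score was 6.16 ± 0.05 in Egfr3, 6.23 ± 0.03 in nrg6 and 6.16 ± 0.04 in nrg7, against 6.20 ± 0.06 in Unc22 (SD, n = 4 each; exact permutation p = 0.371, 0.457 and 0.343). Of the 192 members tested, 2 were higher and 7 lower for Egfr3, 1 and 2 for nrg7, and 0 differed for nrg6. Camera called the list higher for nrg6 with the preset correlation (adjusted p = 0.00152), and that call was lost with an estimated correlation (adjusted p = 0.477). For Egfr3 and nrg7 its adjusted p was 0.799 and 0.704 with an estimated correlation, and fry gave 0.961, 0.356 and 0.698 for Egfr3, nrg6 and nrg7. For Egfr3 the median of the members was 0.04 and their mean -0.02 on the log2 scale, and camera tested on the higher side. For Egfr3, 278 transcripts were higher and 550 lower, for nrg7 105 and 150, and for nrg6 limma called 0, with 2084 at an unadjusted p under 0.05; limma-voom called 3 for nrg6. With the trend with transcript length removed, the Egfr3 calls were 650 higher and 679 lower. SMED30017456 had 4.65 ± 0.66 RPKM in Egfr3 X1 cells against 34.4 ± 1.6 in Unc22 (SD, n = 4 each; log2 fold change -2.65, limma adjusted p = 9.09e-13). Of the transcripts lower in Egfr3 X1 cells, 30.6% were X1-enriched against 51.9% of those tested, with X1 enrichment taken from the nrg6 and nrg7 libraries (Fisher's exact test over transcripts, adjusted p = 7.8e-24). The X1-low score, the mean over transcripts depleted in X1 cells, was 1.35 ± 0.27 in Unc22, 1.56 ± 0.16 in Egfr3, 1.804 ± 0.19 in nrg6 and 1.89 ± 0.50 in nrg7 (SD, n = 4 each), but the list was chosen for low values in these Unc22 libraries, which lowers the Unc22 score. With 200 transcripts chosen over all 4 RNAi groups after the data were seen, the score was 1.63 ± 0.32 in Unc22, 1.63 ± 0.18 in Egfr3, 1.87 ± 0.17 in nrg6 and 1.90 ± 0.43 in nrg7 (SD, n = 4 each; exact permutation p = 0.971, 0.229 and 0.371 against Unc22). Replicates 1 and 2 of Unc22 and nrg6 are among the 16 libraries of 1 profile; with the batch term the counts were 414 for Egfr3, 65 for nrg6 and 146 for nrg7, and a fit of only the groups compared gave 96, 0 and 0. The Egfr3 count was 345, 203, 351 and 481 without Egfr3 replicates 1, 2, 3 and 4, and 402, 528 and 1441 without Unc22 replicates 1, 2 and 3. The nrg7 count was 85, 13, 11 and 28 without nrg7 replicates 1, 2, 3 and 4, and 120, 111, 784 and 121 without Unc22 replicates 1, 2, 3 and 4.

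Fold changes of the knockdowns were compared across transcripts, which are not independent replicates. On SR days 6 to 10 Pearson's r was 0.372 for Egfr3 and nrg7, 0.164 for Egfr3 and nrg6, and 0.664 for nrg6 and nrg7; simulated unchanged groups against the same Unc22 libraries gave 0.502, 0.5 and 0.498. The covariances were 0.00552, 0.00199 and 0.00902 against simulated values of 0.00319, 0.00318 and 0.00314. With the Unc22 libraries split 2 + 2 the mean r was 0.117, -0.089 and 0.333. Egfr3 and nrg6 shared 1 lower transcript (1.05 for independent lists) and 29 higher ones (0.63 for independent lists), and 53 were called in opposite directions. Egfr3 and nrg7 shared 32 lower (6.76) and 53 higher ones (3.69), and nrg6 and nrg7 40 lower (1.27) and 86 higher ones (5.41). The comparisons share the Unc22 libraries, which alone can raise such overlaps above those of independent lists. Shared counts were not simulated for unchanged groups. In X1 cells r was 0.752, 0.595 and 0.674 in the same order, and the simulated r was 0.5, 0.501 and 0.497. The covariances were 0.0608, 0.0410 and 0.0461 against 0.0166, 0.0167 and 0.0165. The simulated spread was pooled over all groups of a fit, while the Unc22 X1 libraries part 2 and 2 on the shared profile. The simulated covariances in X1 cells may therefore be too low. The excess over them does not separate shared knockdown effects from the shared Unc22 libraries.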

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

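The tests of a shared profile, of the label and X1 content of a library that stood apart, of scaling, batch and control libraries for nrg7, the splits that keep pairs at days 0 and 8, and of the change from day 4 to day 10 were chosen only after the results were seen.

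Among 36 groups, the highest or lowest library lay far from the other 3 in a few cases, and chance alone gives this in about 1 of 20 groups. The X1-high score of Egfr3 SR day 10 replicate 1 was 1.282 against 1.174 for its nearest. The normalization factor was 0.7498 in replicate 4 of nrg6 SR day 1 (nearest 1.021), 0.9633 in replicate 4 of Unc22 SR day 4 (nearest 1.003) and 0.895 in replicate 1 of Unc22 X1 (nearest 0.8232).

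The effect of a knockdown on SR days 6 to 10 differed from that on day 0 in 71 transcripts for Egfr3, 6 for nrg6 and 9 for nrg7. From day 4 to day 10 the X1-high score changed less in Egfr3 than in Unc22, by -0.492 (exact permutation p = 0.0286, adjusted p = 0.0629).

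Libraries 3 and 4 of 6 whole-worm groups and 1 and 2 of 2 X1 groups shared a profile. A direction taken from SR day 0 returned in 6 of 34 other groups, of other days and of X1 cells, with absolute correlations of at least 0.43 against at most 0.159 elsewhere, as a batch that the labels do not give would show. Transcript length (correlation -0.045) and depth (a difference of 0.16 M reads) argue against a length bias or a depth difference. No biological explanation was tested, since the profile parts replicates of the same group. It was strong enough that parting replicates 1 and 2 from 3 and 4 gave 4145 calls for Egfr3 and Unc22 at SR day 0 and 4078 for nrg6 and Unc22 in X1 cells, against 30 and 0 for the RNAi itself.

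Replicate 4 of nrg6 SR day 1 deviated from its group with a spread of 1.109 on the log2 scale, against at most 0.338 in other whole-worm libraries. With the trend with length removed its spread was still 3.12 times the highest of the others, so loss of long transcripts does not account for it. The best fitting share of an X1 profile was 0.0055, which argues against X1 cells in the sample. The values also argue against a wrong label within the 36 groups: its highest correlation with any group mean was 0.900, while each of the other 143 libraries reached at least 0.981 with its own group. A sample from outside these groups, or damage to this library, was not tested and stays open, and no biological explanation was tested, since it is a single library.

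For nrg7 on SR days 6 to 10 many small changes were called. Against scaling as the whole cause, 85.2% of the transcripts stayed called under the scaling that kept fewest, and against the 16 libraries of 1 profile, 82.3% stayed called with the batch term. Against chance values of the Unc22 libraries as the whole cause, transcripts called with 6 of the nrg7 libraries showed in the other 6, against nrg6 and Egfr3, a median of 38.1% to 58.4% of that change over 6 ways to halve them; 5 simulations of unchanged groups gave -3.2% to 2.3%. An effect of the nrg7 knockdown may account for the rest, as a hypothesis; a batch that follows the knockdown was not tested.

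Other splits of the same libraries were counted for each comparison. Of 35 splits, only the real 1 gave as many calls for Unc22 X1 against NT (18617, highest other 0), Unc22 SR day 1 (4889, 1130), day 6 (6918, 2156) and day 10 (5612, 1400), for Egfr3 NT day 9 (9, 5), NT day 30 (37, 5) and X1 (828, 1), for nrg6 NT day 30 (25, 2) and SR day 0 (765, 88), and for nrg7 NT day 9 (55, 3), NT day 30 (350, 13), SR day 0 (237, 87) and X1 (255, 1). The same held among 100 splits for SR days 6 to 10 of Egfr3 (475, 191), nrg6 (221, 1) and nrg7 (1343, 301). Each of these comparisons had a share of 0.0286 or 0.01, which adjusts to 0.0429 over the 24 comparisons. These shares are the smallest that 35 and 100 splits allow, and they pass only because many comparisons reach them. The counts therefore argue against chance as a set, but exclude it for no single comparison, and they do not exclude a batch. That holds for the fit of all groups. In a fit of only the groups compared, nrg7 X1 had 0 calls. The counts of Egfr3 in X1 cells, of nrg6 and nrg7 at SR day 0, and of Egfr3 and nrg7 at NT day 9 also fell there, while some others rose. Chance stays open as well for nrg6 NT day 9 (3 of 35, 45), and for the difference from day 0 of nrg6 (5 of 100, 53) and nrg7 (6 of 100, 568). For that of Egfr3, 6 of 100 splits were as large (highest other 4098) when the pairing was ignored. Another 50 splits parted every pair at days 0 and 8, where replicate numbers were taken to pair. Among these only the real 1 was as large (71, highest other 18). Splits of that kind gave at most 229 for Egfr3 on SR days 6 to 10. Where replicate numbers were taken to pair, 35 splits that ignore the pairing were also counted. They gave 1 as large for Unc22 SR day 4 (6342, highest other 3473), 1 for day 8 (4831, 3771) and 2 for Egfr3 SR day 0 (30, 4145). The 8 splits that part all 4 pairs are too few for a share under 0.05. For nrg6 X1, with 0 calls, all 35 of 35 splits are as large by construction (highest other 4078), so they decide nothing. For these 4 the highest other split put replicates 1 and 2 of both groups together, which follows the 16 libraries of 1 profile; for the differences from day 0, the libraries behind the highest split were not examined. Among the 8 splits that part all 4 pairs, the highest other count was 3 for Egfr3 SR day 0, 1207 for Unc22 SR day 4, 726 for Unc22 SR day 8 and 2 for nrg6 X1.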

How the results depend on the processing

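Limma-voom, X1 enrichment or depletion from libraries outside a comparison, the removal of the length trend, the replicate block in a fit of only the groups compared, the batch term, and leaving out the 16 libraries of the shared profile or replicate 4 of nrg6 SR day 1 were chosen after seeing the data. The lower X1-high score of Egfr3 and the higher one of nrg6 on SR days 6 to 10 kept their direction and stayed past the threshold under every alternative run, with -0.419 to -0.398 and 0.129 to 0.154 when each library was left out. The level of the targeted genes and the marker lists by gene name were not run, since the files do not pair IDs with names. With 4 libraries a side, 1.5-fold changes were recovered less often than 2-fold ones in simulated reads (28% against 80% for Egfr3 NT day 30). Where replicate numbers were taken to pair, the replicate block in the fit of all groups moved no count by over 1.5 times. That block is 1 effect per replicate number over all groups, so it cannot follow pairs that only some groups hold. In a fit of only the groups compared, the block moved 2 counts with pairs by over 1.5 times. These were Egfr3 on SR days 6 to 10, where day 8 was taken to pair, and nrg6 in X1 cells. The paired test left the score of single days at an exact p of 0.125. Elsewhere replicates share only a number. The cause of a shift was not tested unless given.

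Late stands for SR days 6 to 10, and for each setting only counts over 1.5 times from the main ones follow, with the ranges over left-out libraries given for every count at the end. With the replicate block in a fit of only the groups compared, the counts were 3085 for Unc22 SR day 1, 97 for Egfr3 NT day 30, 985 for Egfr3 late, 38 for Egfr3 X1, 3 for nrg6 NT day 9, 0 for nrg6 SR day 0, 848 for nrg6 late, 86 for nrg6 late minus day 0, 1 for nrg6 X1, 25 for nrg7 NT day 9, 26 for nrg7 NT day 30, 4 for nrg7 SR day 0, 2536 for nrg7 late and 0 for nrg7 X1. Without a filter on low values, the counts were 24 for Egfr3 NT day 9, 73 for Egfr3 NT day 30, 53 for Egfr3 SR day 0, 542 for Egfr3 X1, 40 for nrg6 NT day 30, 1 for nrg6 X1, 18 for nrg7 late minus day 0 and 76 for nrg7 X1. In a fit of only the groups compared, the counts were 4 for Egfr3 NT day 9, 85 for Egfr3 NT day 30, 4 for Egfr3 SR day 0, 96 for Egfr3 X1, 5 for nrg6 NT day 9, 62 for nrg6 NT day 30, 15 for nrg6 SR day 0, 850 for nrg6 late, 68 for nrg6 late minus day 0, 32 for nrg7 NT day 9, 7 for nrg7 SR day 0, 2712 for nrg7 late and 0 for nrg7 X1. With quantile normalization, the counts were 67 for Egfr3 NT day 30, 54 for Egfr3 SR day 0, 47 for nrg6 NT day 30, 364 for nrg6 late, 13 for nrg6 late minus day 0, 3 for nrg6 X1, 637 for nrg7 NT day 30, 726 for nrg7 SR day 0, 20 for nrg7 late minus day 0 and 569 for nrg7 X1. With limma-voom, the counts were 155 for Egfr3 late minus day 0, 3 for nrg6 X1, 36 for nrg7 NT day 9 and 592 for nrg7 X1. After rescaling by the median ratio, the counts were 1255 for Egfr3 X1, 457 for nrg6 SR day 0, 2 for nrg6 late minus day 0, 4 for nrg6 X1 and 489 for nrg7 X1. With the length trend removed, the counts were 1329 for Egfr3 X1, 14 for nrg6 X1 and 530 for nrg7 X1. With a pseudocount of 0.1, the counts were 2 for nrg6 late minus day 0 and 4 for nrg7 late minus day 0. With the replicate block, the count was 433 for nrg7 X1. Without the 16 libraries, the counts were 3215 for Unc22 SR day 1, 3914 for Unc22 SR day 4, 2903 for Unc22 SR day 8, 17 for Egfr3 SR day 0, 45 for Egfr3 late minus day 0, 327 for Egfr3 X1, 51 for nrg6 SR day 0, 1 for nrg6 late minus day 0, 86 for nrg7 NT day 9, 78 for nrg7 SR day 0, 0 for nrg7 late minus day 0 and 117 for nrg7 X1. With the batch term and without replicate 4 of nrg6 SR day 1, the counts were 7662 for Unc22 SR day 8, 130 for Egfr3 NT day 9, 167 for Egfr3 NT day 30, 86 for Egfr3 SR day 0, 1049 for Egfr3 late, 111 for Egfr3 late minus day 0, 127 for nrg6 NT day 9, 110 for nrg6 NT day 30, 620 for nrg6 late, 79 for nrg6 late minus day 0, 652 for nrg7 NT day 9, 1662 for nrg7 NT day 30, 672 for nrg7 SR day 0, 3162 for nrg7 late and 33 for nrg7 late minus day 0. With the batch term, the counts were 414 for Egfr3 X1, 44 for nrg6 NT day 30, 134 for nrg6 SR day 0, 12 for nrg6 late minus day 0, 65 for nrg6 X1, 99 for nrg7 NT day 9, 102 for nrg7 SR day 0 and 146 for nrg7 X1. Leaving out each library in turn gave 14939 to 17944 for Unc22 X1, 3624 to 7089 for Unc22 SR day 1, 5599 to 8352 for Unc22 SR day 4, 5806 to 9007 for Unc22 SR day 6, 4256 to 6793 for Unc22 SR day 8, 4437 to 7710 for Unc22 SR day 10, 6 to 67 for Egfr3 NT day 9, 22 to 104 for Egfr3 NT day 30, 23 to 68 for Egfr3 SR day 0, 420 to 797 for Egfr3 late, 54 to 96 for Egfr3 late minus day 0, 203 to 1441 for Egfr3 X1, 12 to 48 for nrg6 NT day 9, 16 to 57 for nrg6 NT day 30, 39 to 3222 for nrg6 SR day 0, 171 to 660 for nrg6 late, 0 to 74 for nrg6 late minus day 0, 0 for nrg6 X1 each time, 13 to 342 for nrg7 NT day 9, 205 to 1064 for nrg7 NT day 30, 34 to 1884 for nrg7 SR day 0, 1020 to 3008 for nrg7 late, 2 to 28 for nrg7 late minus day 0 and 11 to 784 for nrg7 X1.

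The X1-high score of nrg7 on SR days 6 to 10 no longer passed unadjusted with quantile normalization (-0.059, exact p = 0.0648), with the median over the list (-0.055, exact p = 0.0877) and without the 16 libraries (-0.047, exact p = 0.109), and lay between -0.076 and -0.047 when each library was left out. It missed the threshold without nrg7 day 6 replicate 2 (-0.053), day 8 replicates 1 and 4 (-0.055 and -0.061) or day 10 replicates 2 and 3 (-0.047 and -0.063), and without Unc22 day 8 replicate 3 (-0.051) or day 10 replicates 3 and 4 (-0.056 and -0.059), with exact p from 0.0502 to 0.07. For Unc22 the paired test, whose smallest p with 4 pairs is 0.125, gave -1.302 on day 1, -1.626 on day 4, -1.531 on day 6, -1.291 on day 8 and -1.038 on day 10. Without the 16 libraries these were -1.241, -1.597, -1.469, -1.279 and -0.976, with too few libraries left to pass. The Egfr3 score on SR day 0, between -0.058 and 0.002 when each library was left out, was 0 without Egfr3 replicate 2 and 0.002 without Unc22 replicate 4, and that of nrg7 on SR day 6, between -0.033 and 0.013, was 0.013 without nrg7 replicate 2. Radiosensitive scores near 0 changed sign in X1 cells: for Egfr3 to 0 with a list of 500 and 0.012 with the median, for nrg6 to -0.015 with quantile normalization, and for nrg7 to 0.006 with the median. That of Egfr3 passed unadjusted on NT day 9 with the median (-0.075, exact p = 0.0286) and in X1 cells with quantile normalization (-0.069, exact p = 0.0286). The radiosensitive score of nrg7 on NT day 9 lay between 0.029 and 0.097 when each library was left out, and passed unadjusted without nrg7 replicate 4 (0.097, exact p = 0.0286). With split controls the late correlations were 0.117 for Egfr3 and nrg7, -0.089 for Egfr3 and nrg6 and 0.333 for nrg6 and nrg7. Those in X1 cells were 0.38, 0.209 and 0.266, and over the splits they ran from 0.235 to 0.471, -0.057 to 0.307 and 0.011 to 0.371. The comparisons then share no control, but each also rests on fewer Unc22 libraries. Some splits set Unc22 replicates 1 and 2 against 3 and 4, which part on the shared profile in X1 cells. Over transcripts called in either comparison, r was -0.076 for Egfr3 and nrg6 late, and 0.882, 0.818 and 0.93 in X1 cells.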

Other observations

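The lists and tests in this part were chosen after the data were seen.

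Among transcripts that fell after irradiation in control worms, those that fell within a day were lower in Egfr3 RNAi worms on SR days 6 to 10. The early-lost score, over 200 transcripts that fell most in Unc22 worms from day 0 to day 1, was lower by 0.432 in Egfr3 than in Unc22 (n = 12 each; exact permutation p = 5.83e-06, adjusted p = 2.75e-05), and 140 of its 200 members were lower and 3 higher. The later-lost list holds the 200 that fell most from day 1 to day 4 in Unc22 worms, among those not called on day 1. Its score differed by -0.05 (exact permutation p = 0.0974, n = 12 each), with 9 of 200 lower. In control worms its median against day 0 was 0.087 on day 8 and 0.092 on day 10. For the early-lost list these were -1.309 and -1.075, so the lists differ in how much loss was left. The difference between both lists was not itself tested. The lists overlap the X1-high list unequally, in 154 and 2 transcripts. Under nrg6 RNAi the early-lost score was higher by 0.156 (exact permutation p = 5.83e-06, n = 12 each) and the later-lost score by 0.03 (exact permutation p = 0.313, n = 12 each).

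The radiation-raised transcripts were higher on SR days 6 to 10 under nrg7 RNAi by 0.432 (n = 12 each; exact permutation p = 5.83e-06, adjusted p = 2.75e-05) and under nrg6 RNAi by 0.216 (exact permutation p = 0.000332, adjusted p = 0.0011, n = 12 each); for Egfr3 the difference was 0.09 (exact permutation p = 0.0403, adjusted p = 0.0831, n = 12 each). On SR day 0 the means over these transcripts were higher too, by 0.276 for nrg7 and 0.238 for nrg6 (n = 4 each). The list was chosen for low values in these Unc22 libraries of day 0. That choice in part raises the day 0 differences and lowers the effect minus that on day 0. In the effect minus that on day 0, 1 of 200 members was higher for nrg7 and 0 for nrg6, and 0 were lower. The list means of that effect, 0.156 and -0.022, were not tested as a score. The X1-low score was higher by 0.145 under nrg7 RNAi (exact permutation p = 0.000105, n = 12 each), while camera's call for that list was lost with an estimated correlation (adjusted p = 0.0811). On day 0 the mean over the X1-low list was already higher by 0.167 (n = 4 each). SMED30029780, which led the X1-high list, went against it: its difference from Unc22 rose from day 0 to days 6 to 10 under Egfr3 RNAi (log2 fold change 1.10) and nrg7 RNAi (1.14). SMED30002142 was higher than in Unc22 at all 8 whole-worm stages in all 3 knockdowns, which share their control libraries.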
